A study of Mus musculus with 16 samples.

How the data were processed

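RNA was measured by sequencing in 16 libraries of cells sorted from mouse femurs at postnatal day 6, 4 libraries in each of 4 groups (PSC, PP1, PP2 and MSC). Per the labels, RNA was extracted with RNeasy Plus Micro, libraries were made with TruSeq RNA, and they were sequenced on a HiSeq4000. The submitters' processing notes name bcl2fastq 2.17, cutadapt, TopHat2 2.0.11, HTSeq 0.6.1, DESeq2 1.6.3 and the mm10 build, without their order. The annotation, filters and strand setting are not given in the sources used here.

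The authors deposited 1 table of signal values, with 22559 genes and 1 column per library. Every value was a whole multiple of a step particular to its library, within a tolerance of 1e-06, so these are gene read counts that the authors divided by 1 size factor per library. They are called normalized counts here. Dividing by the step recovered whole reads, which served for depth and for some alternatives. Read depth ran from 22.3 to 48.4 M recovered reads per library. Library replication, not counting error, set the precision of group means. Gene positions came from GENCODE M21 (GRCm38), which held 21829 of the 22559 identifiers.

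The plan, fixed before the data were examined, used edgeR for raw counts and limma for normalized values. The file holds normalized values, so the limma plan was followed. Genes with a normalized count of at least 10 in at least 4 libraries were kept, 13797 genes. log2(normalized count + 1) was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend, all 16 libraries and group as the only term. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05 and no minimum fold. Folds are 2 to the power of the difference of group means on the log2 scale, and SE is that of this difference. Where every library of a group had no read, the fold was computed against a floor of 3 reads per library and is given as a lower bound, which covers counting error only. Other folds of genes near 0 reads in a group depend on the pseudocount and on single libraries.

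All 6 pairs of groups were compared, and the mean of the 3 mGFP-positive groups was compared with MSC. A gene was called apart in a group when it differed in the same direction from each of the other 3 groups, tested by the largest of the 3 p-values. Of 39 gene lists written before the data were examined (822 members in all), 36 had at least 3 tested genes and were tested with camera at a preset correlation of 0.01. The B cell, T and NK cell and megakaryocyte lists had too few tested genes. Tests were two-sided and adjusted over all lists within a comparison. The same test with an estimated correlation was an alternative. List members were also counted when adjusted over the list alone.

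Genes were named by a rule written in advance. They had to pass the threshold, have no overlap between the libraries of the groups compared, reach at least 8 CPM in the higher group, and carry a symbol that is not a placeholder. Of these, the 8 largest rises and 8 largest falls were taken (5 and 5 for PP1 and PP2 against MSC). For each group the 6 higher and 4 lower genes most apart were taken, and for a list up to 4 members with the smallest adjusted p. Ctsk, Cd200, Eng, Thy1, Enpep and Itgav were always considered. Not every gene that the rule gave is printed. Col2a1 falls outside this rule and was chosen after its values were seen. The 85 duplicated symbols were not named.

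Alternatives chosen in advance were a pseudocount of 0.5 or 8, no filter, at least 50 in 4 libraries, at least 10 CPM in 4 libraries, a replicate block, edgeR 4.0.16 with RLE factors, DESeq2 1.42.0, voom with sample quality weights, a fit of only the 8 libraries compared, and each library left out in turn. The edgeR, DESeq2 and voom alternatives used recovered reads. Alternatives added after seeing the data were edgeR with TMM, rescaling by TMM, leaving out the 3 libraries with the fewest genes, and testing only genes with a read in all libraries. The procedure was tested on simulated data with 13435 genes, using gene means over all 16 libraries and 195 genes changed in PSC. Between PSC and MSC it recovered 10.4% of genes changed 1.5-fold, 34% at 2-fold, 68% at 4-fold and 68% at 8-fold. Of its calls 1.1% were false (1 call). The simulation did not model the larger share of genes at 0 in PSC or the many genes that changed, so these rates may not carry over to the real comparison. No column of the table was left out.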

Results

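The data describe gene expression in 4 cell populations sorted by flow cytometry from femurs of mice at postnatal day 6. The mice carried Ctsk-Cre and the mTmG reporter, which switches a cell and its descendants from membrane Tomato to membrane GFP (mGFP) once the Ctsk promoter has driven Cre. Ctsk encodes cathepsin K, a collagen-cleaving protease. Of the mGFP-positive cells, 3 populations were sorted: periosteal stem cells (PSC) and 2 periosteal progenitor populations, type 1 (PP1) and type 2 (PP2). The mGFP-negative population was labelled endosteal mesenchymal stem cells (MSC). Each group had 4 libraries, 16 in all. The labels place all samples on the same day and in the same litter but do not say that libraries of a group are separate animals, so p-values measure the spread between these samples.

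Read depth was highest in MSC. Recovered reads assigned to genes were 43.72 ± 3.84 M per library in MSC, 31.1 ± 1.92 M in PSC, 27.52 ± 4.59 M in PP1 and 32.88 ± 7.74 M in PP2 (mean ± SD, n = 4 each), over a range of 22.3 to 48.4 M. Genes with at least 1 read numbered 15600 ± 77.7 in MSC, 13310 ± 427 in PSC, 12750 ± 182 in PP1 and 12530 ± 734 in PP2. Of the 13797 genes tested, 0.478% were at 0 reads in an average MSC library, against 7.06% in PSC, 9.80% in PP1 and 11.4% in PP2. Type II collagen (Col2a1), the main cartilage collagen, took 17.9% of the normalized total in MSC, 8.09% in PSC, 5.12% in PP2 and 3.55% in PP1 (group means).

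No clustering was run. On the first 2 principal components PSC and MSC lay apart from each other, and PP1 lay near PP2 replicates 2 and 4. Median Spearman correlations across genes were 0.939 between PSC and MSC libraries, 0.939 between PP1 and PP2, 0.897 between PSC and PP1, 0.893 between PSC and PP2, 0.919 between PP1 and MSC and 0.91 between PP2 and MSC. Within groups the medians were 0.963 in PSC, 0.947 in PP1, 0.941 in PP2 and 0.987 in MSC. Genes are not independent replicates, so no test was attached to these values. PP2 replicates 1 and 3 lay away from the other PP2 libraries, replicate 1 at 141.8 on the fourth component and replicate 3 at -157 on the third.

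**Figure D1:**
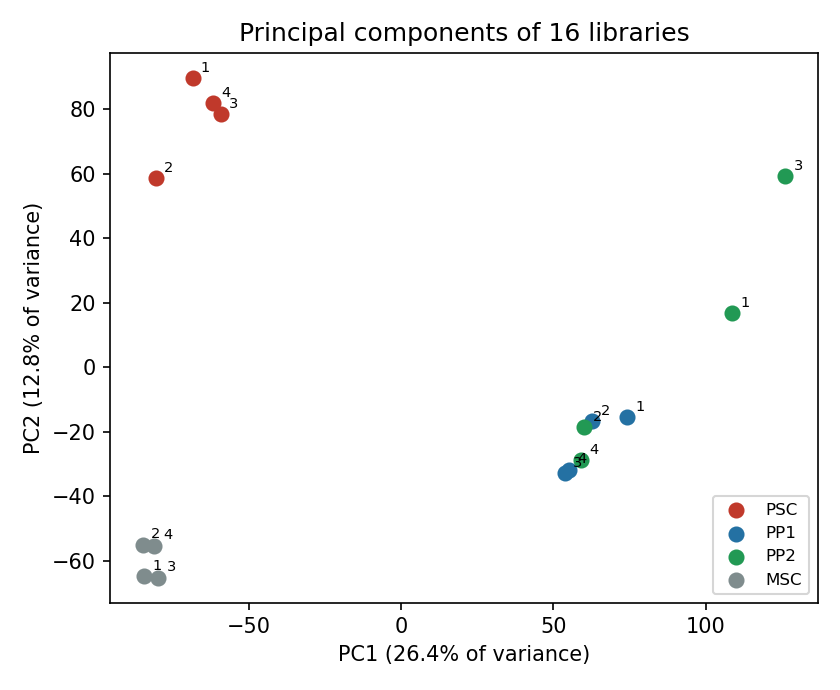
Position of each of the 16 libraries on the first principal component (horizontal axis, 26.4% of variance) and the second (vertical axis, 12.8%), with replicate numbers beside the points and 1 colour per group. PP1 and PP2 lie at positive values of the first component, from 53.7 to 126.2, and PSC and MSC at negative values, parted along the second.

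Transcripts tied to the sort came first, as a check on the labels. The labels do not give the surface gates; in the published description of these populations CD200 and CD105 separate PSC, PP1 and PP2, and a gene whose protein was used to sort is no finding. Cd200 averaged 6098 ± 732 normalized counts in PSC, 818.9 ± 173 in PP1, 2031 ± 410 in PP2 and 4177 ± 654 in MSC (SD, n = 4 each). Eng, which encodes CD105, averaged 4650 ± 954 in PP2 against 376.4 ± 67.3 in PSC, 715.3 ± 121 in PP1 and 469.7 ± 92.4 in MSC. Ctsk averaged 12340 ± 1870 in PP1, 7393 ± 789 in PP2, 2751 ± 558 in PSC and 2082 ± 136 in the mGFP-negative MSC. Cd200 was 7.51-fold higher in PSC than in PP1 (adjusted p = 1.27e-10) and 3.03-fold higher than in PP2 (2.94e-07), while Eng was 12.2-fold higher in PP2 than in PSC (6.02e-11) and 6.44-fold higher than in PP1 (3.54e-07).

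Ctsk was 1.3-fold higher in PSC than in MSC (log2 difference 0.38 ± 0.14 SE, adjusted p = 0.0431) and Cd200 1.47-fold higher (0.55 ± 0.16, adjusted p = 0.0166), while Eng did not pass (log2 difference -0.32 ± 0.19, adjusted p = 0.258). The Ctsk call was lost in 8 of the 16 fits that left out 1 library, with an adjusted p up to 0.152 without PSC replicate 3. The Cd200 call was lost in 2, up to 0.0741 without MSC replicate 3. Itgav, which encodes integrin alpha V, was 1.32-fold lower in PSC than in MSC (adjusted p = 0.0139), a call also lost in 2 of these fits, with an adjusted p up to 0.065 without MSC replicate 3. Thy1 and Enpep, which encode the surface proteins CD90 and aminopeptidase A, were near the floor in PSC, at 11.28 ± 5.31 and 18.07 ± 21.7 normalized counts. In PP1 they averaged 148 ± 51.1 and 141.9 ± 35.1. Enpep averaged 86.59 ± 27.4 in MSC, and the difference to PSC did not pass (log2 difference -3.81 ± 1.51, adjusted p = 0.0715) but did in 5 of 27 alternatives (0.0107 to 0.206 over all). The calls between PSC and PP1 (adjusted p = 0.0248 and 0.028) were lost in 4 and 5 of the fits that left out 1 library, up to 0.0555 without PP1 replicate 2 for Thy1 and 0.0968 without PSC replicate 1 for Enpep.

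**Figure D2:**
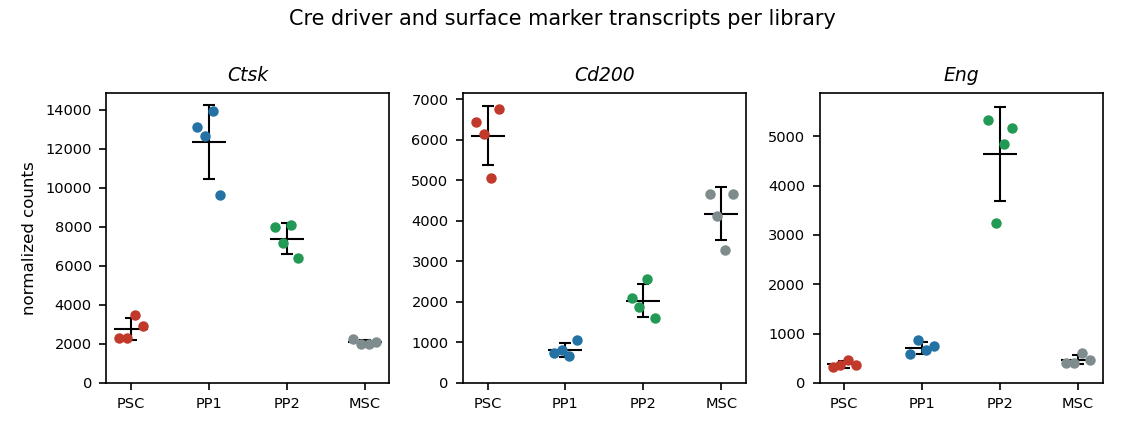
Normalized counts (vertical axes, linear, from 0) of Ctsk, Cd200 and Eng in each library of the 4 groups, with the mean as a long bar and the SD as an error bar (n = 4 each). Cd200 is highest in PSC (5064 to 6748), Eng in PP2 (3252 to 5331) and Ctsk in PP1 (9643 to 13930).

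On the mm10 assembly (GRCm38; 1-based positions of the annotated genes) Ctsk (ENSMUSG00000028111) spans 95499256 to 95509362 on chromosome 3, Cd200 (ENSMUSG00000022661) 45382135 to 45409053 on chromosome 16 and Eng (ENSMUSG00000026814) 32646595 to 32682669 on chromosome 2. Of the genes plotted or used as landmarks further on, Ihh (ENSMUSG00000006538) spans 74945315 to 74951672 on chromosome 1, Dpt (ENSMUSG00000026574) 164796644 to 164824266 on chromosome 1, Foxd3 (ENSMUSG00000067261) 99656299 to 99658622 on chromosome 4 and Col2a1 (ENSMUSG00000022483) 97975602 to 98004695 on chromosome 15.

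PSC were compared with PP1 to see what separates the stem cell sort from a progenitor sort of the same Cre lineage. PSC carried more transcript of growth plate genes and of single osteoblast genes, but not of Bglap (1273 against 1454), and the osteoblast list did not hold with an estimated correlation. Ihh, which encodes a signalling ligand made by prehypertrophic chondrocytes, averaged 23790 ± 2180 normalized counts in PSC and 2399 ± 824 in PP1 (SD, n = 4 each; 10.4-fold, adjusted p = 2.93e-07). Pth1r, the receptor for parathyroid hormone and its related peptide, averaged 56510 ± 7730 and 8672 ± 1070 (6.51-fold, adjusted p = 5.38e-11), and Sp7, which encodes the osteoblast transcription factor osterix, 3216 ± 465 and 573.5 ± 246 (5.97-fold, adjusted p = 1.08e-07). PP1 instead carried connective-tissue transcripts: dermatopontin (Dpt) averaged 7874 ± 2570 in PP1 and 33.6 ± 23.9 in PSC, Cd34 10880 ± 2830 and 377.4 ± 156, and periostin (Postn) 47860 ± 14200 and 3686 ± 1180.

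By list, 17 of 23 chondrocyte genes were higher in PSC than in PP1 and 1 lower, the same counts when adjusted over the list alone, with Hapln1 5.45-fold, Matn3 4.15-fold and Fgfr3 5.12-fold higher (adjusted p of the list = 5.98e-12, and 0.0256 with an estimated correlation). Of 11 hypertrophic chondrocyte genes 8 were higher and none lower, also adjusted over the list alone (2.46e-08, and 0.0233 with an estimated correlation). Among them Alpl, the alkaline phosphatase needed for mineralization, was 6.2-fold higher and Panx3 10.1-fold higher. Pth1r, Mmp13, Alpl, Ibsp, Spp1 and Runx2 stand on both this list and the osteoblast list, so the 2 results overlap. All 19 cholesterol synthesis genes were higher, by both adjustments (2.94e-17, and 0.00584 with an estimated correlation), including Fdps 5.49-fold and Idi1 6.48-fold, enzymes of the mevalonate pathway. Of 25 glycolysis and hypoxia genes 14 were higher and none lower, and 17 higher and 1 lower when adjusted over the list alone (1.91e-09, and 0.0233 with an estimated correlation), with Pgk1 3.44-fold and Tpi1 2.78-fold higher. The osteoblast list had 10 of 22 genes higher and 4 lower (11 and 4 when adjusted over the list alone, adjusted p = 0.00171), but its adjusted p = 0.074 with an estimated correlation. Immediate early genes, which tissue dissociation can induce, were higher in 20 of 28 cases and lower in 2 by both adjustments (Junb 2.95-fold, Btg2 4.47-fold higher; adjusted p = 1.55e-07, and adjusted p = 0.0626 with an estimated correlation).

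Lists lower in PSC than in PP1 were led by the fibroblast list, with 18 of 20 genes lower and 1 higher (19 and 1 when adjusted over the list alone; adjusted p = 3.7e-20, and 0.00419 with an estimated correlation). Clec3b was 85.6-fold lower, Igfbp6, an insulin-like growth factor binding protein, 21.1-fold, and Cd248 8.19-fold. Of 19 skeletal stem and periosteal marker genes 15 were lower and none higher by both adjustments, with Cd34 30-fold and Pdgfra 6.8-fold lower (5.5e-12, and 0.0168 with an estimated correlation). Of 15 tendon and ligament genes 11 were lower and 2 higher (13 and 2 when adjusted over the list alone), including Kera 34.3-fold and Tnmd 5.12-fold lower (1.59e-07, and 0.0414 with an estimated correlation). FGF and IGF signalling genes were lower in 17 of 26 cases and higher in 1 (18 and 1 when adjusted over the list alone; 1.62e-08, and 0.0105 with an estimated correlation). Matrix protease and inhibitor genes were lower in 20 of 32 and higher in 3 (21 and 3 when adjusted over the list alone; 3.24e-08, and 0.00539 with an estimated correlation). Collagens split, with 20 of 32 lower, such as Col3a1 8.2-fold and Col4a1 7.43-fold, and 9 higher by both adjustments (adjusted p = 7.27e-05, and adjusted p = 0.218 with an estimated correlation). Osteoclast genes moved with this comparison: 8 of 11 were lower in PSC (9 when adjusted over the list alone; 2.9e-05, and 0.0445 with an estimated correlation), among them Acp5, which encodes tartrate-resistant acid phosphatase, 12-fold lower.

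In total 4301 genes differed between PSC and PP1, 2224 higher and 2077 lower in PSC, and 2415 by over 2-fold. With DESeq2 2184 of 4399 were higher, and 1762 of 3565 without PSC replicate 2. Among the largest rises were Serpina1b and Serpina1d (no read in PP1, at least 96.8-fold and at least 77.9-fold; paralogs, and reads shared between them were not tested), Mypn, Olfr874, Klk10, Fcer2a and Mcoln3. The largest falls were Col6a6 (log2 difference -9.52 ± 0.77), Dpp4 (no read in PSC, at least 147-fold lower), Dpt, Myoc, Cadm3, Gpnmb, Dkk2, which encodes a Wnt antagonist, and Htra4, with adjusted p between 3.6e-09 and 1.87e-05. Col6a6 averaged 4.646 ± 9.29 in PSC, so near 0 that the size of its difference depends on the pseudocount and on single libraries. The 2 groups' libraries did not overlap for 3470 of the 4301 genes, which the test had already selected. Of all 13797 genes 28.9% did not overlap, where chance gives 2.86%. Klk10, Fcer2a and Mcoln3 lost their calls with edgeR and with DESeq2 on recovered reads, and their adjusted p over all alternatives ran from 1.21e-05 to 0.148, from 7.05e-05 to 0.183 and from 0.000314 to 0.189.

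**Figure D3:**
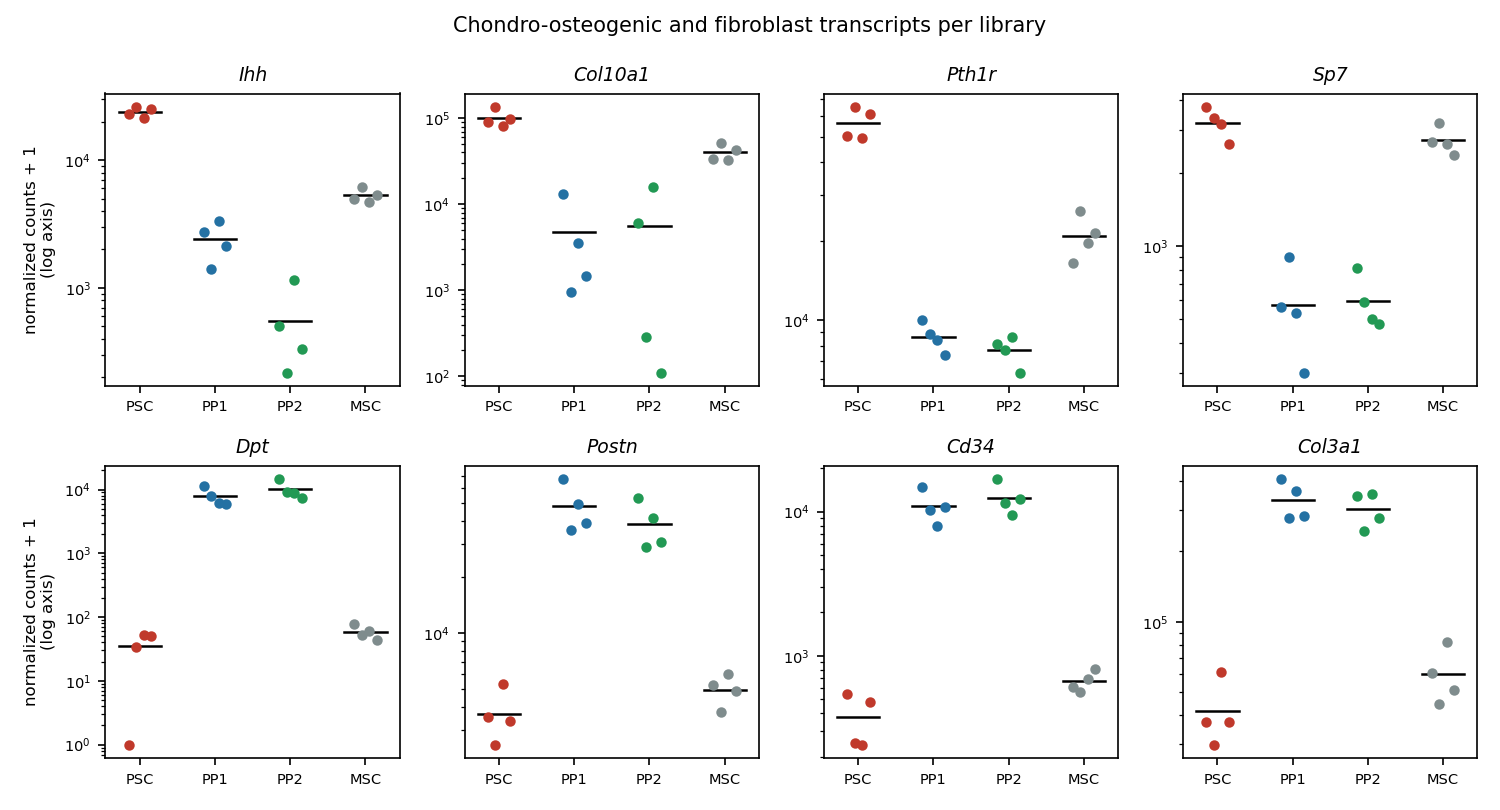
Normalized counts plus 1 (vertical axes, log scale) of 4 growth plate or osteoblast genes (top row) and 4 connective-tissue genes (bottom row) in each library, with a bar at the arithmetic mean of the 4 libraries of a group. Ihh lies at 21190 or more in the PSC libraries and at 3344 or less in those of PP1 and PP2, while Dpt lies at 51.29 or less in PSC and at 5946 or more in PP1 and PP2.

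PSC were set against PP2 with the same question. Ihh, Panx3 and Car12 differed by more than between PSC and PP1, which is the difference of PP1 and PP2 themselves (5.04-fold, 2.54-fold and 9.08-fold higher in PP1; adjusted p = 0.00165, 0.0134 and 2.25e-05). The calls of Panx3 and Car12 were lost in 1 alternative each (0.0516 without PP1 replicate 1 and 0.35 with voom). Ihh averaged 552.7 ± 421 in PP2 (52.2-fold higher in PSC, adjusted p = 2.65e-10), Panx3 was 25.7-fold higher in PSC and Car12, a carbonic anhydrase, 91.3-fold higher. Dpt averaged 10080 ± 3200 in PP2, Cd34 12500 ± 3120 and Clec3b 10830 ± 3330, the last against 153.7 ± 59.9 in PSC. Acta1, skeletal muscle actin, averaged 2826 ± 1060 in PP2, 1090 ± 447 in PP1 and 41.77 ± 13 in PSC, and did not pass between PP1 and PP2 (adjusted p = 0.105).

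Chondrocyte genes were higher in PSC than in PP2 in 16 of 23 cases and lower in 1 (17 and 1 when adjusted over the list alone; adjusted p = 7.67e-11, and 0.03 with an estimated correlation). Hypertrophic chondrocyte genes were higher in 9 of 11 and lower in none (10 when adjusted over the list alone; 2.17e-09, and 0.0172). Osteoblast genes were higher in 14 of 22 and lower in 5 (15 and 5 when adjusted over the list alone; 1.45e-05, and 0.03). The 19 cholesterol synthesis genes were again all higher by both adjustments, Sqle by 6.24-fold (5.21e-18, and 0.00659). Glycolysis and hypoxia genes were higher in 16 of 25 cases and lower in 2 by both adjustments (1.93e-08, and 0.03). Immediate early genes were higher in 19 of 28 and lower in 1 (20 and 1 when adjusted over the list alone; 1.74e-08, and 0.0477). Fibroblast genes were lower in PSC in 18 of 20 cases and higher in 1 by both adjustments (3.01e-19, and 0.00514), with Mfap5, a microfibril protein, 37.3-fold lower. Skeletal stem and periosteal markers were lower in 14 of 19 and higher in 1 by both adjustments (1.7e-09, and 0.03). Tendon and ligament genes were lower in 11 of 15 and higher in 1 by both adjustments (1.39e-06, and 0.0477). FGF and IGF genes were lower in 18 of 26 and higher in 1 (20 and 1 when adjusted over the list alone; 6.85e-09, and 0.0088), with Spry1, a feedback inhibitor of FGF signalling, 17.1-fold lower. Protease and inhibitor genes were lower in 18 of 32 and higher in 3 (21 and 3 when adjusted over the list alone; 3.08e-07, and 0.00659). In each pair of values the second is the adjusted p with an estimated correlation. The muscle list had 6 of 8 genes lower in PSC and 1 higher by both adjustments (adjusted p = 0.00183, and adjusted p = 0.123 with an estimated correlation). The osteoclast list, which passed between PSC and PP1, did not pass here, with 4 of 11 genes lower in PSC and none higher (5 when adjusted over the list alone; adjusted p = 0.135, and 0.431 with an estimated correlation).

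Between PSC and PP2 4520 genes differed, 2422 higher and 2098 lower in PSC, and 2574 by over 2-fold. Among the largest rises were Cbln2 (log2 difference 9.09 ± 0.86), Serpina1b and Serpina1d (no read in PP2, at least 112-fold and at least 90.3-fold higher), Mcoln3, St8sia6, Relt and Mypn. Leading the falls were Col6a6 (log2 difference -10.04 ± 0.77), Dpt, Ly6h (no read in PSC, at least 160-fold lower), Myoc, Myl1, a skeletal muscle myosin light chain, Cadm3, Htra4 and Dkk2, with adjusted p between 6.4e-09 and 8.22e-06. Cbln2 averaged 6.879 ± 13.8 in PP2 and Col6a6 4.646 ± 9.29 in PSC. Both are so near 0 that the size of these 2 differences depends on the pseudocount and on single libraries. Libraries of PSC and PP2 did not overlap for 3562 of the 4520 genes, and for 28.5% of all genes tested. Mcoln3 lost its call with DESeq2 on recovered reads, and its adjusted p over all alternatives ran from 4.96e-05 to 0.064.

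**Figure D4:**
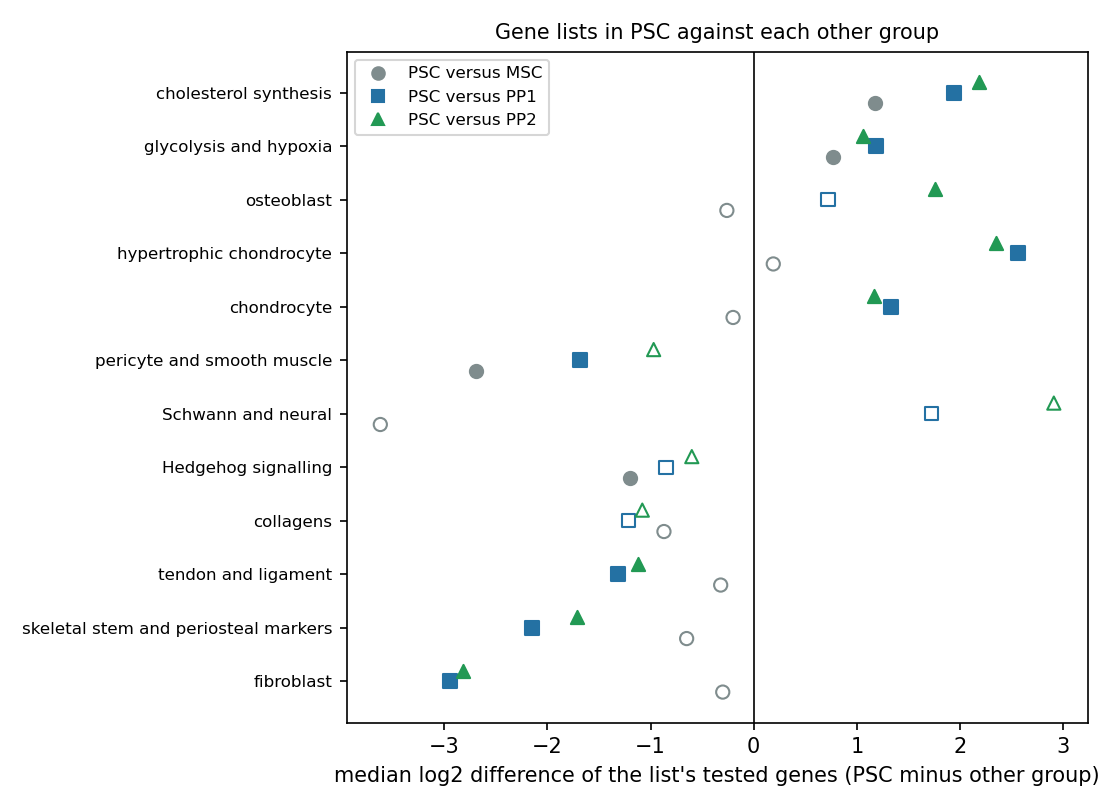
Median log2 difference of the tested genes of 12 lists (horizontal axis, PSC minus the other group) against MSC, PP1 and PP2. Filled symbols mark an adjusted p under 0.05 with an estimated correlation and open symbols the others. The fibroblast list lies at -2.94 against PP1, -2.82 against PP2 and -0.30 against MSC, and the cholesterol list at 1.94, 2.18 and 1.18.

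PSC and MSC were compared to set the periosteal stem cells beside the endosteal population. PSC carried more transcript of cholesterol synthesis and glycolysis genes, and less of perivascular and marrow stromal genes. The lower Schwann list did not hold with an estimated correlation, and the chondrocyte and hypertrophic lists did not pass. Ihh averaged 23790 ± 2180 in PSC and 5288 ± 641 in MSC (SD, n = 4 each; 4.51-fold, adjusted p = 0.000139), Fdps 9562 ± 1930 and 2941 ± 626 (3.26-fold, adjusted p = 1.29e-06), and Ldha, lactate dehydrogenase, 49900 ± 7410 and 16910 ± 3060 (2.96-fold, adjusted p = 4.01e-07). Cxcl12, a chemokine of marrow stromal cells, averaged 2479 ± 883 in PSC and 9512 ± 3160 in MSC (3.84-fold lower, adjusted p = 0.000136), and Prg4, which encodes the joint lubricant lubricin, 1772 ± 433 and 49540 ± 17700 (27.5-fold lower, adjusted p = 1.64e-08). Foxd3 and Sox10, transcription factors of the neural crest and Schwann lineage, averaged 801.5 ± 118 and 1803 ± 216 in MSC, against 9.202 ± 16.2 and 72.43 ± 44.6 in PSC.

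Cholesterol synthesis genes were higher in PSC than in MSC in 15 of 19 cases and lower in none (16 when adjusted over the list alone; adjusted p = 2.15e-12, and 0.0185 with an estimated correlation). Glycolysis and hypoxia genes were higher in 15 of 25 and lower in 1 (15 and 3 when adjusted over the list alone; 2.43e-09, and 0.0282 with an estimated correlation), with Pgk1 2.61-fold and Bnip3 3-fold higher. Ribosomal protein genes were higher in 42 of 46 cases (44 when adjusted over the list alone; Rps2 1.76-fold; 3.62e-20) and oxidative phosphorylation genes in 22 of 34 (26 when adjusted over the list alone; 2.94e-12), with none lower in either list, but both had an adjusted p = 0.216 with an estimated correlation. Hedgehog genes were lower in 12 of 16 cases and higher in 1, Ihh, by both adjustments (7.39e-06, and 0.0297 with an estimated correlation): Gas1, a co-receptor, was 5.95-fold lower and Hhip, a target and inhibitor of the pathway, 4.32-fold lower. Notch genes were lower in 6 of 16 and higher in none by both adjustments, with Notch3 5.96-fold lower (0.00067, and 0.0185 with an estimated correlation). Pericyte and smooth muscle genes were lower in 9 of 12 and higher in none (11 when adjusted over the list alone; Mcam 8.12-fold, Acta2 7.91-fold lower; 3.2e-07, and 0.0185 with an estimated correlation). Marrow stroma and adipocyte genes were lower in 11 of 21 and higher in none (14 when adjusted over the list alone; Apoe 4.26-fold lower; 5.8e-05, and 0.0297 with an estimated correlation). Matrix protease and inhibitor genes were lower in 18 of 32 and higher in 3 (19 and 3 when adjusted over the list alone; Mmp14 2.6-fold lower; 5.17e-06, and 0.0185 with an estimated correlation).

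Collagen genes were lower in PSC than in MSC in 17 of 32 cases and higher in none (20 when adjusted over the list alone; Col18a1 6.95-fold and Col4a1 5.71-fold lower, both of basement membranes; 1.82e-09), with an adjusted p = 0.11 with an estimated correlation. Articular and groove of Ranvier genes were lower in 10 of 12 and higher in 1 by both adjustments (1.88e-05, and adjusted p = 0.144 with an estimated correlation). Schwann and neural genes were lower in 9 of 12 and higher in 1, S100b, by both adjustments (0.0024, and adjusted p = 0.0913 with an estimated correlation). The chondrocyte list as a whole did not pass, with 7 of 23 genes higher and 5 lower (7 and 6 when adjusted over the list alone; adjusted p = 0.533). Nor did the hypertrophic list, with 4 of 11 higher and 2 lower (4 and 3 when adjusted over the list alone; adjusted p = 0.116). Within them Hapln1 was 3.13-fold, Panx3 3.99-fold and Pth1r 2.71-fold higher in PSC, and Mmp13, collagenase 3 of hypertrophic cartilage and bone, 3.09-fold lower.

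Between PSC and MSC 3630 genes differed, 1670 higher and 1960 lower in PSC; by over 2-fold, 239 were higher and 1348 lower. Which direction held more genes depended on the tool and filter: 1804 of 3320 were higher with edgeR and TMM, 1629 of 3249 with edgeR and RLE, 1788 of 3355 at 10 CPM and 1741 of 3479 for genes with a read in all libraries. The largest rises were Cbln2, Dnajc22, Fxyd2, Ppa1, an inorganic pyrophosphatase (65540 ± 7140 and 12030 ± 2950; 5.54-fold, adjusted p = 7.84e-07), H2-DMa, Car12, Ihh and Ddit4l. The largest falls were Foxd3 (log2 difference -7.67 ± 0.98, with a range given under the genes apart), Col20a1, Pou3f1, Plxnb3, Gas7, Cldn11, Myh11 and Ttyh1, with adjusted p between 1.7e-05 and 0.0131. PSC and MSC libraries did not overlap for 3352 of the 3630 genes, and for 38.7% of all genes tested. Cbln2 lost its call in 2 of the 16 fits that left out 1 library (adjusted p up to 0.0562 without PSC replicate 2), Dnajc22 in 8 (up to 0.108 without MSC replicate 3) and Ttyh1 in 1 (0.0502 without PSC replicate 1). Foxd3 lost its call in none of these but did so with a filter of 10 CPM (0.139; over all its alternatives 1.02e-07 to 0.139). The MSC libraries were deeper and had fewer genes at 0, as given above, and the median log2 difference of all genes tested was -0.18.

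PP1 and PP2 were compared to see what separates the progenitor types, and few genes passed the threshold. That does not show the other genes to be alike, since 1791 of 13797 had an unadjusted p under 0.05 in this fit. Single bone-cell and osteoclast genes were among those higher in PP1, while neither list held with an estimated correlation. Bglap, which encodes osteocalcin, averaged 1454 ± 639 in PP1 and 188.2 ± 124 in PP2 (8.49-fold, adjusted p = 0.000571), Ihh was 5.04-fold higher (adjusted p = 0.00165) and Acp5 averaged 3448 ± 2550 and 687 ± 255 (4.47-fold, adjusted p = 0.0039). PP2 carried more Omd, an osteoblast and connective-tissue proteoglycan (22450 ± 652 against 6007 ± 1150; 3.79-fold, adjusted p = 1.69e-06), and more Adh1, an alcohol dehydrogenase (1161 ± 350 against 271.3 ± 109; 4.38-fold, adjusted p = 0.00251).

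Osteoclast genes were higher in PP1 than in PP2 in 3 of 11 cases and lower in none (6 when adjusted over the list alone; adjusted p = 3.84e-07, and adjusted p = 0.0934 with an estimated correlation): Acp5, Atp6v0d2 (81.2-fold) and Dcstamp (no read in PP2, at least 33.5-fold), the last 2 needed for the fusion of osteoclast precursors. Osteoblast genes were higher in 3 of 22 and lower in none (6 and 1 when adjusted over the list alone; 0.000283, and adjusted p = 0.192 with an estimated correlation), namely Car12, Bglap and Ifitm5. Skeletal muscle genes had no member past the threshold over all genes and 4 of 8 lower in PP1 when adjusted over the list alone (0.000107, and adjusted p = 0.192 with an estimated correlation). Endothelial genes were higher in 2 of 17 and lower in none (4 when adjusted over the list alone; 0.000107, and adjusted p = 0.277 with an estimated correlation). Macrophage and monocyte genes were higher in 2 of 14 and lower in none (5 when adjusted over the list alone; 0.00395, and adjusted p = 0.376 with an estimated correlation). Fibroblast genes showed 0 of 20 members past the threshold by either adjustment, with a median log2 difference of 0.05.

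Between PP1 and PP2 115 genes differed, 66 higher and 49 lower in PP1, and 105 of the 115 had no overlap between libraries, as did 4.7% of all genes tested. The majority was not stable: 18 of 45 were higher in PP1 with voom, 33 of 82 for genes with a read in all libraries, 36 of 79 at 10 CPM, 42 of 85 with edgeR and 14 of 28 in a fit of these 8 libraries. Named by rank were Ccl9 (no read in PP2, at least 99-fold higher in PP1), Atp6v0d2, Slc9b2, Crtac1, Car3, Car12, Bglap and Ihh, and lower in PP1 Eng, Adh1, Omd, Fam211b, Gsg1l, Tmem117, Cd200 and Slco2b1. The count was 45 with voom, 28 in a fit of these 8 libraries alone, 227 with a replicate block, 419 with DESeq2 on recovered reads and 181 without PP2 replicate 4. Calls lost when 1 library was left out were those of Crtac1 in 10 of 16 fits (adjusted p up to 0.0912 without PP2 replicate 1), Slc9b2 in 5 (0.0917 without PP1 replicate 2) and Gsg1l in 4 (0.0632 without PP1 replicate 4). Slco2b1 lost its call in 4 (0.0579 without PP2 replicate 3) and Dcstamp in 2 (0.0717 without PP1 replicate 2). Atp6v0d2 and Dcstamp also lost their calls with edgeR and TMM (0.0812 and 0.0708). Without the 3 libraries with the fewest genes they lost them too (0.112 and 0.107). Atp6v0d2 averaged 4.946 ± 8.61 in PP2, so near 0 that its fold depends on the pseudocount and on single libraries. Voom kept the calls of Ihh, Acp5, Eng, Adh1, Omd and Cd200 and of no other gene named in these 3 paragraphs on PP1 and PP2.

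**Figure D5:**
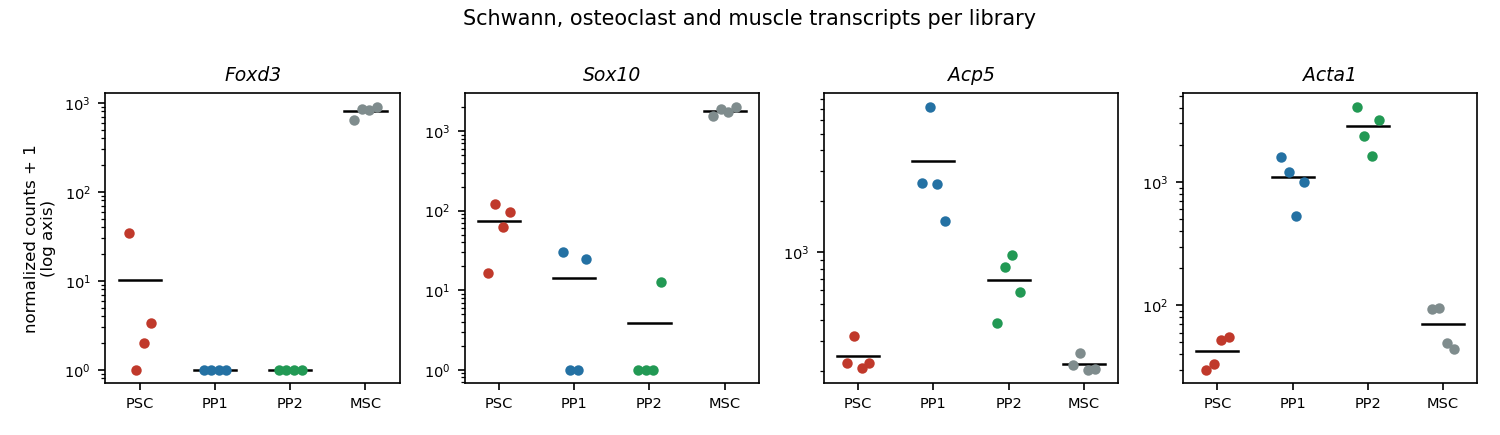
Normalized counts plus 1 (vertical axes, log scale) of the Schwann-lineage genes Foxd3 and Sox10, the osteoclast gene Acp5 and the skeletal muscle gene Acta1 in each library, with a bar at the arithmetic mean of the 4 libraries of a group. Foxd3 and Sox10 are highest in MSC, Acp5 in PP1 (1535 to 7202) and Acta1 in PP2 (1634 to 4093).

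Set against MSC, PP1 carried more connective-tissue transcript and less of growth plate, bone and Schwann-lineage genes. Keratocan (Kera) averaged 8017 ± 2620 in PP1 and 48.23 ± 20.3 in MSC (SD, n = 4 each; 168-fold, adjusted p = 4.46e-10) and Clec3b 12530 ± 3490 and 111.3 ± 32.2 (112-fold, adjusted p = 2.52e-11). Fibroblast genes were higher in PP1 in 17 of 20 cases and lower in 1 (19 and 1 when adjusted over the list alone; adjusted p = 5.14e-26, and 0.00129 with an estimated correlation). Skeletal stem and periosteal markers were higher in 10 of 19 and lower in none (11 and 3 when adjusted over the list alone; 2.05e-09, and 0.0299 with an estimated correlation). Chondrocyte genes were lower in 20 of 23 and higher in 1 (21 and 1 when adjusted over the list alone; Col9a2 4.87-fold and Col11a2 5.48-fold lower; 1.37e-16, and 0.0185 with an estimated correlation). Osteoblast genes were lower in 12 of 22 and higher in 3 (13 and 3 when adjusted over the list alone; Sp7 5.05-fold lower; 8.57e-06, and 0.0299 with an estimated correlation). Schwann and neural genes were lower in 10 of 12 and higher in 1 by both adjustments (1.06e-06, and 0.0185 with an estimated correlation), with Foxd3 at 0 reads in PP1 (at least 230-fold lower). The call of this list was lost on genes with a read in all libraries (adjusted p = 0.225).

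In all 2958 genes differed between PP1 and MSC, 1225 higher and 1733 lower in PP1, with 2681 not overlapping (30.1% of all genes tested). By over 2-fold, 454 were higher and 1157 lower in PP1. The median log2 difference of all genes tested was -0.18, and -0.009 with a filter of 10 CPM. PP1 libraries had more genes at 0 than MSC libraries, and loss of low-abundance transcripts in PP1 was not tested. The rule named Kera, Dpt, Clec3b, Chodl and Gpr1 as the largest rises and Krt79 (no read in PP1, at least 331-fold lower), Foxd3, Erbb3, Col20a1 and Sox10 as the largest falls. Immediate early genes were lower in 21 of 28 cases and higher in 1 (23 and 1 when adjusted over the list alone; Fos 2.79-fold lower; 1.25e-11, and 0.0299 with an estimated correlation). Osteoclast genes were higher in 6 of 11 and lower in none (6 and 1 when adjusted over the list alone; 0.00137, and adjusted p = 0.13 with an estimated correlation). The Foxd3 call was lost with a filter of 10 CPM (adjusted p = 0.0797; 8.16e-09 to 0.0797 over its alternatives), and the osteoclast list did not pass with that filter or on genes with a read in all libraries.

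PP2 was compared with MSC in the same way. Fibroblast genes were higher in PP2 in 19 of 20 cases and lower in 1 by both adjustments (adjusted p = 1.69e-24, and 0.00171 with an estimated correlation; Mfap5 79.6-fold and Igfbp6 27.6-fold higher). Hypertrophic chondrocyte genes were lower in 11 of 11 by both adjustments (Ihh 11.6-fold lower; 9.06e-12, and 0.0116 with an estimated correlation). Chondrocyte genes were lower in 20 of 23 and higher in none by both adjustments (Acan, the main cartilage proteoglycan, 3-fold lower; 7.91e-16, and 0.0145 with an estimated correlation). Osteoblast genes were lower in 16 of 22 and higher in 1 (16 and 3 when adjusted over the list alone; Alpl 5.71-fold lower; 1.68e-09, and 0.0116 with an estimated correlation). Cholesterol synthesis genes were lower in 14 of 19 and higher in none by both adjustments (1.07e-09, and 0.0247 with an estimated correlation). Schwann and neural genes were lower in 10 of 12 and higher in 1 by both adjustments (1.73e-06, and 0.0145 with an estimated correlation). This list lost its call on genes with a read in all libraries (adjusted p = 0.254). Skeletal muscle genes were higher in 5 of 8 and lower in none by both adjustments (Acta1 40.2-fold; 2.65e-05, and adjusted p = 0.0593 with an estimated correlation). Skeletal stem and periosteal markers were higher in 11 of 19 and lower in 3 (11 and 4 when adjusted over the list alone; 9.05e-07), but not with an estimated correlation (adjusted p = 0.0593). The osteoclast list did not pass, with 2 of 11 genes higher and 3 lower by both adjustments (adjusted p = 0.837).

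The count for PP2 and MSC was 3307 genes, 1280 higher and 2027 lower in PP2, with 2935 not overlapping (30.5% of all genes tested). By over 2-fold, 460 were higher and 1452 lower in PP2. The median log2 difference of all genes tested was -0.195, and -0.001 with a filter of 10 CPM. PP2 libraries too had more genes at 0 than MSC libraries, and loss of low-abundance transcripts in PP2 was not tested. Named as the largest rises were Ly6h, Coch, Dpt, Clec3b and Col6a6, and as the largest falls Ednrb, an endothelin receptor of neural crest cells (log2 difference -10.54 ± 1.12), Krt14, Erbb3 and Egfl8, with no read in PP2 (at least 381-fold, at least 340-fold and at least 312-fold lower), and Sox10 (log2 difference -9.89 ± 1.18). Adjusted p of these 10 genes lay between 1.02e-10 and 3.36e-05. Ednrb and Sox10 averaged 0.8357 ± 1.67 and 2.925 ± 5.85 in PP2, so near 0 that the size of their differences depends on the pseudocount and on single libraries.

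The mean of the 3 mGFP-positive groups was also set against MSC, as a contrast of all Cre-lineage sorts with the Cre-negative sort, and 3037 genes differed, 1248 higher and 1789 lower in the mGFP-positive mean. Ctsk itself was 3-fold higher (log2 difference 1.59 ± 0.11, adjusted p = 1.15e-08), by group 1.3-fold in PSC, 5.88-fold in PP1 and 3.54-fold in PP2. Fibroblast genes were higher in 15 of 20 cases and lower in 1 (16 and 1 when adjusted over the list alone; adjusted p = 6.42e-19, and 0.00555 with an estimated correlation). This rise came from PP1 and PP2: between PSC and MSC 4 of 20 were higher and 7 lower in PSC, and the list did not pass (4 and 8 when adjusted over the list alone; adjusted p = 0.153, and 0.507 with an estimated correlation). Schwann and neural genes were lower in 10 of 12 and higher in none (11 and 1 when adjusted over the list alone; 1.54e-07, and 0.0186 with an estimated correlation). Notch genes were lower in 7 of 16 and higher in none (10 when adjusted over the list alone; 0.00179, and 0.0363 with an estimated correlation), but the list did not pass for PP1 alone (adjusted p = 0.147). Erythroid genes had 3 of 7 members higher in the mGFP-positive mean (4 and 1 lower when adjusted over the list alone), and the list did not pass (adjusted p = 0.06). Hbb-bs, a globin, averaged 1647 ± 1000 in PSC, 2505 ± 1990 in PP1, 1127 ± 845 in PP2 and 331.6 ± 314 in MSC. The number of genes was 5907 with voom, 1922 without MSC replicate 1 and 1679 without MSC replicate 3.

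Genes apart in 1 group are those higher than in each of the 3 other groups or lower than in each. Their number depends on how near the nearest group lies, and only 115 genes differed between PP1 and PP2. A low count therefore does not show that a group lacks a profile of its own. Cd200 and Eng, tied to the sort, are among the genes called. PSC had 1383, 757 higher and 626 lower. Ppa1 was 5.54-fold, H2-DMa, an antigen-loading protein, 5.15-fold, Car12 5.01-fold and Ihh 4.51-fold higher in PSC than in its nearest group (adjusted p between 1.06e-06 and 0.000244), Fxyd2 5.7-fold (0.00202) and Cbln2 7.44-fold (0.0353). Gpnmb, Ccbe1, Cadm3 and Htra4 were lower in PSC than in each other group, at PSC means of 4.526 ± 9.05, 6.732 ± 9.98, 3.017 ± 3.58 and 22.14 ± 31.8, so near 0 that their folds depend on the pseudocount and on single libraries. The log2 difference of Gpnmb ran from -6.62 without PSC replicate 2 to -3.29 with a pseudocount of 8. MSC had 231, 173 higher, led by Foxd3 (801.5 against 9.202 in PSC, its nearest group, where 1 library held most of the reads; log2 difference 7.67, from 5.92 with a pseudocount of 8 to 8.72 without PSC replicate 1), Col20a1, Pou3f1, Plxnb3, Reln and Kcna1, and 58 lower, among them Kera, Crabp1, Gpha2 and Spon2. PP1 had 17, of which 4 were higher, among them Acp5 (4.47-fold), Ctsk (1.66-fold) and Tgfbi (1.63-fold), and 13 lower, among them Omd (3.79-fold), Tmem117, Cd200 and Clec3a. Acp5 stands on the osteoclast list, and which cells of the PP1 sort carried the Acp5 and Ctsk transcripts was not tested. PP2 had 21, of which 5 were higher, among them Eng (6.44-fold), Adh1 (4.38-fold), Lsp1 and Pdgfrl, and 16 lower, among them Cbln2, Gpr56, Car12 (9.08-fold) and Car3 (6.62-fold).

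Several of these calls rested on 1 library or 1 setting. Without 1 library, calls were lost for Cbln2 in PSC (adjusted p up to 0.12 without PSC replicate 2) and Htra4 in PSC (0.0525 without PSC replicate 2). In PP1 and PP2 they were lost for Acp5, Ctsk and Tmem117 in PP1 (0.0534, 0.136 and 0.075, each without PP2 replicate 4) and Lsp1 in PP2 (0.0577 without PP1 replicate 4). In MSC they were lost for Pou3f1 (0.0526 without MSC replicate 1), Reln (0.143 without PSC replicate 3), Kcna1 (0.0789 without MSC replicate 1) and Gpha2 (0.0907 without MSC replicate 4). The MSC count was 98, 133 and 103 without MSC replicates 1, 2 and 3. Other settings also ended calls, and the ranges of adjusted p that follow are over all alternatives of a gene. In MSC a filter of 10 CPM ended those of Foxd3 (2.47e-06 to 0.553), Pou3f1 (0.00013 to 0.0664), Reln (0.000493 to 0.172) and Kcna1 (0.000272 to 0.46). DESeq2 ended those of Plxnb3 in MSC (1.24e-05 to 0.0959) and Htra4 in PSC (0.000476 to 0.176), and voom that of Kera in MSC (6.26e-05 to 0.1). In PP2 voom ended those of Cbln2 (3.5e-06 to 1), Gpr56 (4.85e-05 to 0.61), Car12 (1.5e-22 to 1) and Car3 (1.56e-09 to 0.837), and in PP1 that of Tmem117 (0.000258 to 0.315). Without the 3 libraries with the fewest genes, calls ended for Acp5 (6.54e-08 to 0.109), Ctsk (0.000167 to 0.136), Tgfbi (3.14e-06 to 0.146) and Cd200 (1.21e-10 to 0.0556) in PP1. The same was seen for Lsp1 (5.93e-05 to 0.0971) and Pdgfrl (2.36e-06 to 0.18) in PP2 and Gpha2 (0.00172 to 0.0907) in MSC. Cbln2 in PSC (0.000629 to 0.12) also lost its call with a pseudocount of 0.5 and without a filter. The PP2 count was 33 without PP2 replicate 3, and further counts by tool and filter are given under the processing alternatives.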

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

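The tests of cells of all types, of a single chondrocyte composition and of hypertrophic chondrocytes were chosen only after their results were seen. Single libraries stood apart from the other 3 of their group in 8 of 164 groups of 4, where chance gives about 1 in 20, or 8.2. They were Alpl in PSC replicate 2 (18870 normalized counts, others 13790 to 14530), Bglap in MSC replicate 2 (1584, others 821.3 to 941.7) and Foxd3 in PSC replicate 1 (33.48, others 0 to 2.323). Next were Sox10 in PP2 replicate 4 (11.7, others 0) and Fdps in PP1 replicate 2 (2100, others 1577 to 1616). The last were Acp5 in PSC replicate 2 (321.8, others 209.2 to 223.2), Omd in PSC replicate 1 (38840, others 25040 to 26490) and Adh1 in PP2 replicate 1 (1683, others 929.2 to 1028).

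Of the 1587 genes that differed over 2-fold between PSC and MSC, 84.9% were higher in MSC. Read depth is argued against: MSC libraries thinned to the mean PSC depth still averaged 15455 genes with a read (lowest 15373), against 13919 in the highest PSC library. Loss of low-abundance transcripts in PSC stays open, since among genes with a mean of at least 500 the share was 70.2% (exact 95% interval 66.5 to 73.7), between the bounds set in advance. Among the most abundant genes tested this way it was 50.8% (43.5 to 58.1). Genes with 1 to 9 reads numbered 721 ± 315 in PSC libraries and 2236 ± 87 in thinned MSC libraries (SD, n = 4 each). In PP1 and PP2, where such loss was not tested, they numbered 298 ± 101 and 257 ± 66. A wider mix of cells in MSC, or its own expression, may also give the larger share higher in MSC and was not tested.

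Schwann-lineage genes were higher in MSC than in the mean of the other groups, with a median log2 difference of 5.38. An equal rise of all other cell types over the mean of the other groups was not seen. Whether a lower share of the sorted cells in MSC raised some of these types cannot be told. Erythroid, neutrophil and skeletal muscle genes had a median of -1.7 (25 genes, 7 called lower and 0 higher). Its interval, -2.43 to -0.1, is across genes, which are not independent replicates. The median also depends on the other sorts, where Acta1 averaged 2826 in PP2 and 1090 in PP1 against 69.43 in MSC. Hbb-bs too was lowest in MSC, so the median cannot decide the question. Endothelial (2.31), pericyte and smooth muscle (1.05) and macrophage genes (0.89) went the other way, so the types did not move alike, and a higher share of some of them in MSC stays open. Schwann-lineage cells or their RNA in the MSC sort stay a possible explanation. Of a second list of 22 Schwann genes, 45.5% were higher in MSC than in PSC and 1 was lower, between the bounds set in advance, and 4 of them had a mean of at least 500 in PSC too. Sox10 averaged 1803 in MSC and Foxd3 801.5, the gates that would remove such cells are not in the labels, and expression by the endosteal cells themselves was not tested.

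Chondrocyte genes were higher in PSC than in PP1. Chondrocytes of a single composition at a higher share in PSC stay open: the log2 differences of 28 abundant chondrocyte genes had an SD of 1.3 between genes, but genes that other PP1 cells also express would differ less at any share, so this spread decides nothing. Hypertrophic or prehypertrophic chondrocytes within the PSC sort are a candidate explanation, since 11 hypertrophic genes exceeded 23 other chondrocyte genes by 1.23 on the log2 scale (medians 2.56 and 1.33; two-sided permutation p = 0.029 across genes, which are not independent replicates). The same gap would arise from a single composition if other PP1 cells express fewer hypertrophic genes. Pth1r, Mmp13, Alpl, Ibsp, Spp1 and Runx2 are also members of the osteoblast list, so the gap cannot tell hypertrophic chondrocytes from osteoblast-lineage expression. Expression of these genes by the periosteal stem cells themselves would give the same values and was not tested.

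Chance as the source of the numbers of changed genes was tested with other splits of the libraries. For each of the 6 pairs of groups only 1 of the 35 splits, the real one, gave as many genes. That is the smallest share these splits can give, and the 6 pairs were not adjusted for. Mixed splits put different sorts in 1 group, which widens the spread and leaves few calls. The splits therefore do not by themselves exclude chance. The highest other split gave 0 genes for PSC and MSC (real 3630), 4 for PSC and PP1 (4301), 12 for PSC and PP2 (4520), 25 for PP1 and PP2 (115), 0 for PP1 and MSC (2958) and 0 for PP2 and MSC (3307). Over 100 regroupings of all libraries, with the same limit, only the real grouping gave as many genes for the mGFP-positive mean against MSC (3037, highest other 62). The same held for genes apart in PSC (1383 and 5), PP2 (21 and 1) and MSC (231 and 4). For genes apart in PP1 (17), 2 of 100 gave as many, the other being a regrouping with the 4 PSC libraries in place of PP1 (1201), which reflects the structure of the samples.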

How the results depend on the processing

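The tests with edgeR and TMM, TMM rescaling, no 3 libraries with the fewest genes, and only genes with a read in all libraries were chosen after seeing the data. Counts of changed genes stayed within 1.5 times except as follows, and the cause was not tested. With voom, PSC and MSC gave 5797 genes (3630 as reported), the mGFP-positive mean 5907 (3037), PP1 and PP2 45 (115), apart PP2 7 (21) and apart MSC 450 (231). With DESeq2, PP1 and PP2 gave 419, apart PP1 55 (17) and apart PP2 110. Apart MSC gave 531 without a filter, 146 with edgeR and RLE and 141 with edgeR and TMM. Only the 8 libraries of PP1 and PP2 gave 28 genes, and fewer samples estimate the spread there. Without the 3 libraries with fewest genes, apart PP1 gave 9. A replicate block gave 227 for PP1 and PP2, including all 115, and 365 for apart MSC. The rule set in advance for pairing, that every same-number pair have r over 0.1, was not met (2 of 24 did), and the fits reported use no block. The mean r was still larger than in any other arrangement of the numbers (exact permutation p of the mean r = 7.23e-05, the smallest it can give). Same-numbered libraries were therefore more alike than under any other numbering, by a small mean r of 0.048. Whether they share an animal or a pool is not in the labels, and the p-values reported do not account for it. With 1 library left out, counts ran from 2532 to 3968 (PSC and MSC), 3565 to 4691 (PSC and PP1), 3792 to 4638 (PSC and PP2), 89 to 181 (PP1 and PP2; 181 without PP2 replicate 4), 2174 to 3322 (PP1 and MSC), 2407 to 3428 (PP2 and MSC) and 1679 to 3476 (mGFP-positive mean; 1922 without MSC replicate 1, 1679 without MSC replicate 3). Apart counts ran from 1023 to 1476 (PSC), 12 to 20 (PP1), 16 to 33 (PP2; 33 without PP2 replicate 3) and 98 to 256 (MSC; 98, 133 and 103 without MSC replicates 1, 2 and 3). No named gene or list reversed, but the majority among called genes turned in some fits. Of PSC and MSC genes 1670 of 3630 were higher in PSC, but 1804 of 3320 with edgeR and TMM and 1788 of 3355 at 10 CPM. Of PSC and PP1 genes 2224 of 4301 were higher in PSC, but 2184 of 4399 with DESeq2 and 1762 of 3565 without PSC replicate 2. The mGFP-positive mean had 1343 of 2653 higher at 10 CPM, and apart PP2 4 of 7 with voom. Of the PSC and MSC genes 3154 were shared with edgeR and TMM and 3373 with DESeq2, 0 of opposite sign. The share of PP1 and PP2 genes higher in PP1 was 57.4%, but 40% with voom, 40.2% for genes with a read in all libraries and 45.6% at 10 CPM. The median log2 difference of all genes, PSC minus MSC, was -0.18, against -0.141 rescaled by TMM, -0.038 with edgeR and TMM and 0.038 at 10 CPM. For named genes in pairs, other settings gave 8568 unchanged calls, 183 lost and 20 gained, and leaving out 1 library 10817, 328 and 7. For named apart genes these were 394 unchanged and 45 lost, and 514 and 46. An estimated correlation ended the call in 64 of 216 list tests. On genes with a read in all libraries, a filter that drops genes at 0 by construction, the Schwann list lost its call against MSC in each group. The adjusted p was 0.424 for PSC, 0.225 for PP1 and 0.254 for PP2. In groups at 0 reads, the bound that 3 reads per library allow covers counting error only. Depth alone did not set the zeros: Enpep was at 0 in PP2 replicate 1 (28.7 M reads) but at 368.5 in PP2 replicate 3 (24.3 M reads). The true difference may therefore be smaller than the bound.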

Other observations

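The test of Y-linked genes was chosen after the result was seen. Summed normalized counts of 4 Y-linked genes were at least 3619 in replicates 2 and 3 of every group and at most 7.351 in replicates 1 and 4. A candidate explanation is that same-numbered libraries come from the same animal or pool. The same numbers were high in all 4 groups in a share of 0.00463 of the 216 arrangements of 2 high libraries per group, though sexes matched by number over different animals would give it too.

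Other lists fixed before the data were examined gave these results between PSC and MSC, as members higher and lower in PSC and adjusted p with the preset correlation. Osteoclastogenic and vascular factors had 0 and 8 of 17 (0.000371; 0.0185 with an estimated correlation). FGF and IGF genes had 2 and 12 of 26 (0.00067), cell cycle genes 0 and 8 of 40 (0.00081), and unfolded protein and secretory stress genes 10 and 2 of 21 (0.00557), none of which held with an estimated correlation (0.0894, 0.282 and 0.216). Skeletal stem and periosteal markers had 2 and 8 of 19 (0.0218, and 0.0849 without PSC replicate 2) and endothelial genes 0 and 2 of 17 (0.0329, and 0.166 without PSC replicate 1). Neither held with an estimated correlation (0.314 and 0.35). Not passing were sort surface markers (2 and 4 of 12, 0.225), osteoblast (3 and 4 of 22, 0.827), osteocyte (0 and 1 of 9, 0.623), tendon (3 and 4 of 15, 0.57) and fibroblast genes (4 and 7 of 20, 0.153). Nor did osteoclast (0 and 3 of 11, 0.0768), macrophage (0 and 0 of 14, 0.533), neutrophil (0 and 0 of 10, 0.533), mast cell (0 and 0 of 3, 0.954), erythroid (2 and 0 of 7, 0.116) and muscle genes (1 and 1 of 8, 0.954). The last were immediate early (2 and 8 of 28, 0.623), Wnt (4 and 11 of 36, 0.0872), BMP and TGF-beta (4 and 12 of 41, 0.153), Hox (0 and 6 of 27, 0.113) and interferon genes (0 and 3 of 13, 0.0872). The test compares a list with all other genes, and where its sign differed from the list's median or mean the list did not pass, as for chondrocyte genes between PSC and MSC (median -0.2, mean 0.02, test up).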
